A study of Mus musculus with 11 samples.

How the data were processed

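RNA from the neural tissue of 11 mouse embryos at embryonic day 9.5 was measured, 1 library per embryo. Per the labels' protocols, polyadenylated RNA was made into Illumina TruSeq libraries and run on a HiSeq 2000 instrument. The authors deposited whole-number counts per Entrez gene, with the gene length, for 27179 genes in each library. Per the submitters' processing notes, reads were counted with featureCounts on the mouse build mm10. The aligner, the tool versions, the strand setting and the annotation release are not given in the sources used here. The counts are raw: totals per library ranged from 8211942 to 11218682. A deposited table of the whole series held the same values gene by gene and was not used here.

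Group and replicate number were taken from the sample titles: 4 affected females, 4 control males and 3 control females. The replicates are separate embryos in the labels' wording. No batch, litter or sequencing date is in the labels, so none could be tested. The replicate numbers were not taken to pair embryos across groups. Within groups, library pairs differed by a chi-square of 2.73 to 31.6 per degree of freedom over genes with at least 20 counts in the pair, well above sampling noise, so no library was counted as a duplicate. Control females 2 and 3 were the closest pair, with 2.73.

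Entrez identifiers were matched to symbols and positions with a RefSeq gene table of the assembly GRCm38.p6, which has the same coordinates as mm10, and 18 more symbols came from GENCODE vM21. In total 25293 identifiers had a symbol and 1886 had none. GC content per gene came from the GENCODE transcripts and was known for 95.9% of tested genes. Gene lists written before the data were examined held 28 sets: p53 targets, X inactivation centre RNAs, genes reported to escape X inactivation, Y-linked genes, silencing factors, apoptosis, cell cycle, neural tube closure, neural cell types and patterning, and other cell types and stress responses.

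Differential expression was computed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14542 genes, and libraries were scaled by TMM. All 11 libraries entered 1 quasi-likelihood fit with the group as the only factor, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 11.9%. Log2 CPM used a prior count of 2. For each library, the median of X-linked genes without Xist minus that of autosomal genes was taken after centring each gene on the mean of all libraries, and groups were compared by a two-sided exact permutation test. Gene lists were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over the 28 lists. Of the lists called with the preset, none of 8 for affected against control females kept its call with the estimated correlation. The numbers were 2 against 14 for affected females against control males (Y-linked genes and genes that escape X inactivation) and 4 against 7 for control males against control females (these 2 lists, the X inactivation centre and p53 targets).

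Named genes followed a rule written before the data were examined. They were Trp53, Bcl2l11, Xist and the detected Y-linked genes, and per comparison the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 2 and ranges that do not overlap. To these came up to 4 members of each list with the smallest adjusted p, and the 10 genes with the smallest larger p in both comparisons of affected females. Not every gene that the rule took is given in the text. Gstm6, Erdr1 and Gm4983, which lay among 15 shared calls, and any other gene named only in the closing section were chosen after their values were seen.

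The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 changed genes, and these recovery rates hold for the simulated comparison alone. For affected against control females, with 14405 genes, it recovered 49.3% of 1.5-fold, 71.6% of 2-fold and 97.0% of 4-fold changes. For affected females against control males, with 14410 genes, these were 55.2%, 88.1% and 95.5%, and for control males against control females, with 14388 genes, 34.3%, 83.6% and 89.4%. The alternatives were RLE scaling, TMM from autosomal genes, other expression filters, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, other sets of libraries, and robust fitting. Removal of length and GC trends, omission of control female 1 with control male 4, and the replicate block in camera for all gene lists were added after the data were seen.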

Results

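Neural tissue from 11 mouse embryos at embryonic day 9.5 was profiled by sequencing of polyadenylated RNA. The tissue was the brain, cut just behind the otic vesicle, which is the primordium of the inner ear. The mice were C57BL/6 compound mutants for Trp53, which encodes the tumour suppressor p53, and Bcl2l11, which encodes the pro-apoptotic protein Bim. Per the labels, 4 affected females and 4 control males were p53-/- Bim+/-, and 3 control females were p53+/+ Bim+/-. The labels do not say in what way the affected females were affected; loss of p53 is known to lead to failure of neural tube closure mainly in female mouse embryos. The affected females held 10088058, 9965900, 11173484 and 10638145 counts (replicates 1 to 4), the control males 10264119, 9188848, 10089377 and 11218682 counts, and the control females 8211942, 9209181 and 10632842 counts (replicates 1 to 3). Levels below are TMM-normalised CPM (counts scaled to a common library size), as mean ± SD over the embryos of a group, with n = 4 affected females, 4 control males and 3 control females. Fold changes, their standard errors (SE) and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14542 genes.

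The targeted genes and the sex-linked genes were examined first, as a check of the labels. Trp53 (chromosome 11, 69580348 to 69591873 in GRCm38) did not separate the genotypes at the level of whole-gene counts. Its level was 139, 111, 125 and 107 CPM in the affected females, 127, 132, 131 and 112 CPM in the control males, and 125, 107 and 105 CPM in the control females. Counts over the whole gene do not show which exons were lost, so the p53 genotypes rest on the labels here. Ccng1, a cyclin gene that p53 activates directly, did separate them: it lay between 21.8 and 33.5 CPM in the 8 p53-/- libraries and between 74.7 and 93.8 CPM in the 3 p53+/+ libraries. Bcl2l11 (chromosome 2, 128126038 to 128162547) was at 43.7 ± 4.29 CPM in affected females, 40.2 ± 5.12 CPM in control males and 76.7 ± 5.56 CPM in control females, although all 3 groups carry the same Bim label. It was lower than in control females by a log2 fold change of -0.81 (SE 0.11, adjusted p = 0.000851, edgeR) in affected females and -0.93 (SE 0.11, adjusted p = 0.000217, edgeR) in control males. The 4 Y-linked genes that passed the expression filter, Kdm5d, Uty, Ddx3y and Eif2s3y, had 95.5, 54.7, 102 and 100.2 CPM in control males and a mean of at most 0.383 CPM in either female group. No library went against its sex label.

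**Figure D1:**
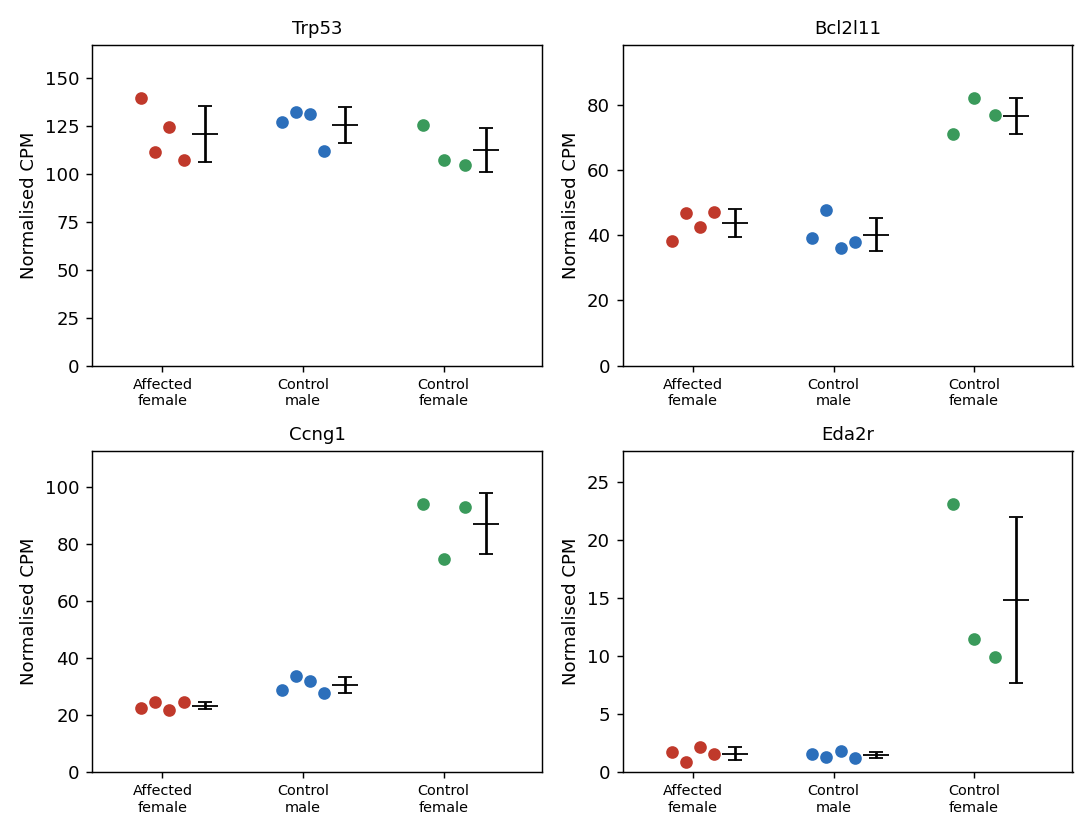
Normalised CPM of Trp53, Bcl2l11, Ccng1 and Eda2r (vertical axes, from 0) in each embryo of the 3 groups; points are embryos, and the bar beside them is the mean with its SD. Trp53 overlaps between groups, while Ccng1 in the 3 control females, at 74.7 to 93.8 CPM, lies above all 8 p53-/- embryos.

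Affected females were then compared with control females, which differ in p53 genotype and in being affected. Xist, the RNA that coats and silences the inactive X chromosome, fell from 5044 ± 816 CPM in control females to 1722 ± 337 CPM in affected females, 2.93-fold (log2 fold change -1.55, SE 0.16, adjusted p = 0.000144, edgeR), against 10.2 ± 2.07 CPM in control males. In all, 4073 of 14542 tested genes changed, 1889 upward and 2184 downward. The upward share of 46.4% was 33.5% to 47.8% leaving out 1 library. Of the 4073 genes, 116 rose and 588 fell at least 2-fold. The count depended on single libraries: it was 1967 without affected female 3, 2605 without affected female 4, 1924 without control female 2 and 1663 without control female 3. With limma voom and sample weights it was 7639.

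The transcripts of the X inactivation centre, the region that holds Xist, fell in affected females relative to control females for 4 of 7 measured members and rose for none (camera adjusted p = 0.0218; adjusted p = 0.58 with an estimated correlation; 1 rose and 4 fell adjusted over the list alone). Xist lies on chromosome X at 103460373 to 103483233. Tsix, which overlaps it on the other strand, fell by 1.33 on the log2 scale (SE 0.14, adjusted p = 0.000204, edgeR), but the strand setting of the counting is not given in the sources used here, so reads of the pair cannot be assigned with certainty. The span of Tsix, 103431517 to 103484957, holds all of Xist. In control males against control females Tsix stood at -8.47 beside -8.96 for Xist, so Tsix may not be a separate fall. The non-coding RNAs Ftx and Jpx, both activators of Xist, stood at -0.67 (SE 0.18) and -0.77 (SE 0.24). Without control female 1 the set was not called (camera adjusted p = 0.087).

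The X chromosome as a whole moved the other way. The median level of 528 X-linked genes without Xist, relative to autosomal genes and centred on the mean of all libraries, was 0.13 ± 0.06 (log2, SD, n = 4) in affected females and -0.05 ± 0.04 (n = 3) in control females. The difference was 0.18, or 13.4%, and all 4 affected females lay above all 3 control females (two-sided exact permutation test, p = 0.0286, the smallest p that 35 splits allow, adjusted p = 0.0429 over 3 comparisons). Of the X-linked genes 29.7% were called higher and 10.0% lower, against 12.6% and 14.9% of autosomal genes. The rise was spread along the chromosome: the median was positive in each of 9 windows of 20 Mb, from 0.04 to 0.34, whereas the medians of the 19 autosomes lay between -0.06 and 0.05. Camera on the X-linked genes gave p = 4.37e-06 with a preset correlation and p = 0.0363 with an estimated correlation. Among X-linked genes, Capn6 (a calpain-like protein), Irs4 (an adaptor of insulin signalling) and Maob (monoamine oxidase B) rose by log2 fold changes of 1.13 (SE 0.15), 1.09 (SE 0.14) and 1.36 (SE 0.18). Genes reported to escape X inactivation went both ways, with 6 of 19 higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.665). This list shares Xist, Jpx and Ftx with the X inactivation centre list, so part of its falls repeats that list. The actin regulator Shroom4 and the deubiquitinase gene Usp9x rose by 0.67 (SE 0.11) and 0.60 (SE 0.12), while Mid1, which spans the pseudoautosomal boundary and varied among control females (315 ± 177 CPM), stood at -1.78 (SE 0.24). Kdm6a, at 145 ± 5.43 CPM, had a log2 fold change of 0.02 (SE 0.08, adjusted p = 0.86, edgeR).

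**Figure D2:**
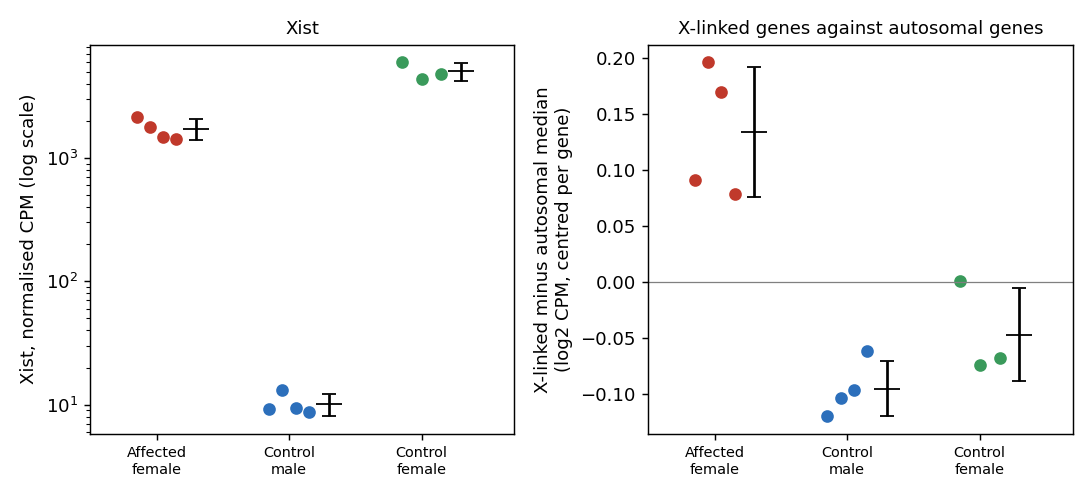
Left, Xist in normalised CPM on a log axis; right, the median of X-linked genes minus that of autosomal genes in log2 CPM centred per gene. Points are embryos and the bar beside them is the group mean with its SD; affected females had less Xist than control females (1722 against 5044 CPM) and the highest X-linked medians (0.13 against -0.05).

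Of 26 measured early neuron markers, 16 fell in affected females and none rose (19 fell adjusted over the list alone; camera adjusted p = 5.44e-05; adjusted p = 0.667 with an estimated correlation). Nhlh1 and Nhlh2, transcription factors of newly born neurons, fell, with log2 fold changes of -2.16 (SE 0.35) and -2.41 (SE 0.48), and Isl1, a motor and sensory neuron factor, stood at -1.27 (SE 0.24). The neuron-specific host gene of the microRNA miR-124, Mir124a-1hg, was among the 8 largest falls, at -3.45 (SE 0.67). Control female 1 stood apart from the other control females for this list, with a list median of -0.35 against 0.53 and 0.59 in replicates 2 and 3 and between -0.70 and -0.18 in affected females. Neural progenitor markers were mixed, with 5 of 20 higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.812): Lin28a, an RNA-binding protein of early embryonic cells, rose by 0.95 (SE 0.23) and Sox21 by 0.56 (SE 0.12), while Fabp7, a radial glia gene, stood at -1.68 (SE 0.28) and the Notch ligand gene Dll1 at -0.61 (SE 0.17).

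The lists of surface ectoderm, neural crest, neural tube closure and cell cycle genes were called upward by camera with the preset correlation, and none of them with an estimated correlation (adjusted p = 0.572 to 0.861 with an estimated correlation). Of 18 surface ectoderm and otic epithelium markers, 11 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 9.32e-05; adjusted p = 0.572 with an estimated correlation). Grhl2 and Grhl3, transcription factors of surface ectoderm, rose by 0.82 (SE 0.15) and 1.37 (SE 0.28), and the tight junction gene Cldn4 by 0.85 (SE 0.15). The list median of control female 1 was -0.01 against -0.34 and -0.47 in control females 2 and 3 and 0.24 to 0.48 in affected females. Of 16 neural crest markers, 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00091; adjusted p = 0.572 with an estimated correlation), among them Ets1 with 0.94 (SE 0.12) and Sox10 with 1.10 (SE 0.19). Of 44 neural tube closure genes, 14 rose and 4 fell (16 and 4 adjusted over the list alone; camera adjusted p = 0.00236; adjusted p = 0.667 with an estimated correlation). The actin nucleator gene Cobl rose by 1.43 (SE 0.23) and Gli3, a repressor of Hedgehog targets, by 0.65 (SE 0.13), while Dvl1, a Wnt signalling gene, fell by 0.74 (SE 0.12). G1/S and S phase genes rose for 14 of 25 and fell for 1 (16 and 2 adjusted over the list alone; camera adjusted p = 0.000646; adjusted p = 0.667 with an estimated correlation), with Mcm5 at 0.44 (SE 0.11). G2/M genes rose for 3 of 25 (7 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0153; adjusted p = 0.861 with an estimated correlation), with Plk1 at 0.69 (SE 0.13), and were not called without affected female 3 (camera adjusted p = 0.0503). Control female 1 also had the highest list median among control females for neural tube closure (0.02 against -0.15 and -0.11) and G2/M genes (0.02 against -0.09 and -0.07), with at least 0.08 in affected females for both. The same held for neural crest markers (-0.10 against -0.19 and -0.29) and G1/S genes (-0.07 against -0.16 and -0.11). Affected females had at least 0.135 and 0.08 for these lists.

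Expression of p53 target genes was lower in affected females than in p53+/+ control females for 12 of 38 measured members and higher for none (also 12 adjusted over the list alone; camera adjusted p = 0.000361; adjusted p = 0.172 with an estimated correlation). Ccng1 fell from 87.1 ± 10.7 to 23.2 ± 1.38 CPM (log2 fold change -1.91, SE 0.10, adjusted p = 9.27e-08, edgeR). Eda2r, a receptor gene, stood at -3.22 (SE 0.31), and the thiamine transporter gene Slc19a2 at -1.09 (SE 0.15). Genes of the BCL-2 family and caspases did not move together (4 of 25 rose and 3 fell, the same counts adjusted over the list alone; camera adjusted p = 0.665): Bmf, a pro-apoptotic relative of Bim, rose by 0.99 (SE 0.13) while Bcl2l11 fell.

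Ventral neural tube genes fell in affected against control females for 7 of 19 members and rose for none (8 fell adjusted over the list alone; camera adjusted p = 0.0506), with the Hedgehog target Gli1 at -0.89 (SE 0.14) and Nkx2-1 at -1.31 (SE 0.29). Forebrain and midbrain pattern genes included 3 that rose and 2 that fell of 22 (camera adjusted p = 0.442), and hindbrain genes 4 that rose and 1 that fell of 12 (camera adjusted p = 0.519), with Hesx1 at 1.98 (SE 0.33) and Egr2 at 1.78 (SE 0.33). Glycolysis and hypoxia genes rose for 10 of 24 and fell for 1 (11 and 3 adjusted over the list alone; camera adjusted p = 0.125). The list median of control female 1 was 0.31 against -0.35 and -0.28 in control females 2 and 3 and 0.06 to 0.54 in affected females. The glucose transporter gene Slc2a3 rose by 1.08 (SE 0.25) and Ldha by 0.68 (SE 0.16), while Vegfa fell by 1.02 (SE 0.17). Of 15 genes encoded by mitochondrial DNA, 13 fell, with a median log2 fold change of -1.31. Mitochondrial counts made up 1.31% to 1.69% of a library in affected females against 2.48% to 4.99% in control females. The share was 2.48% in control female 1 and 4.59% and 4.99% in control females 2 and 3. Imprinted genes fell for 9 of 25 and rose for 3 (10 and 7 adjusted over the list alone; camera adjusted p = 0.589), with the maternally expressed RNA Meg3 at -1.22 (SE 0.23). None of 17 primitive erythroid markers was called (camera adjusted p = 0.714, with a median of -0.17 although the test pointed upward), and the embryonic globin gene Hbb-bh1 stood at 627 ± 242 against 1312 ± 937 CPM.

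The remaining lists were not called as sets against control females. Of 27 silencing factors that act with Xist, 4 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.219), with the DNA methyltransferase gene Dnmt1 at 0.47 (SE 0.13) and the Polycomb gene Ring1 at -0.95 (SE 0.24). Dorsal neural tube genes fell for 3 of 18 (2 adjusted over the list alone; camera adjusted p = 0.582), with the Wnt agonist gene Rspo3 at -0.77 (SE 0.21). Head mesenchyme markers rose for 2 of 21 (camera adjusted p = 0.525), with Meox1 at 2.05 (SE 0.47), and endothelial markers fell for 2 of 18 (1 adjusted over the list alone; camera adjusted p = 0.274), with Tie1 at -0.48 (SE 0.13). Of 4 macrophage and microglia markers 2 fell (3 adjusted over the list alone; camera adjusted p = 0.125), both near the floor, with Csf1r at 0.221 ± 0.169 against 1.39 ± 1.02 CPM. Endoderm and yolk sac markers rose for 1 of 9 and for none adjusted over the list alone (camera adjusted p = 0.932), and cardiac muscle markers rose for 1 and fell for 2 of 5 (camera adjusted p = 0.767). Interferon response genes rose for 1 and fell for 3 of 11 (camera adjusted p = 0.665), with Ifit2 at 0.83 (SE 0.17) and Stat2 at -0.61 (SE 0.17). Integrated stress response genes rose for 3 and fell for 2 of 17 (4 and 2 adjusted over the list alone; camera adjusted p = 0.713), with the serine enzyme gene Shmt2 at 0.41 (SE 0.11) and Trib3 at -1.19 (SE 0.29). Immediate early and heat shock genes rose for 1 and fell for 1 of 12 (0 and 1 adjusted over the list alone; camera adjusted p = 0.767). The fall was that of the heat shock gene Hspa1b, which had 96.3 CPM in control female 1 and 0.53 and 0.834 CPM in control females 2 and 3. The 4 Y-linked genes were not called in this comparison (camera adjusted p = 0.713).

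**Figure D3:**
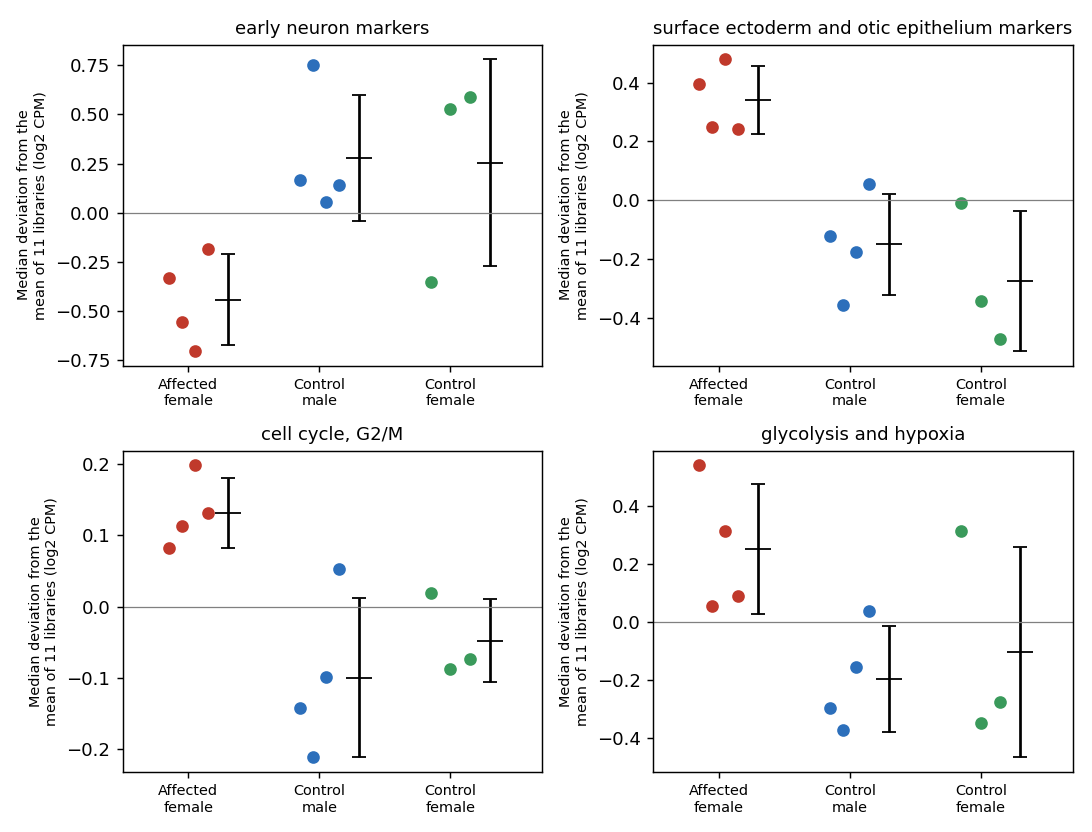
Median deviation of each embryo from the mean of all 11 libraries (log2 CPM) over the members of 4 gene lists; points are embryos, and the bar beside them is the group mean with its SD. Early neuron markers lie below 0 in all 4 affected females and in control female 1 (-0.35), and surface ectoderm and otic markers are highest in affected females.

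Affected females and control males share the p53-/- Bim+/- genotype and differ in sex and in being affected. In all, 2940 of 14542 genes changed, 1383 upward and 1557 downward. Of these, 74 rose and 244 fell at least 2-fold. The count was 361 without affected female 3, 1174 without affected female 4, 658 without control male 1, 1132 without control male 2, 1470 without control male 3 and 5140 without control male 4. It was 6397 with limma voom and sample weights. It was 6014 without control female 1 and control male 4, an alternative added after the data were seen.

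X-linked genes stood at -0.10 ± 0.02 in control males (SD, n = 4) relative to autosomal genes, 0.23 below the affected females, or 17.2% (two-sided exact permutation test, p = 0.0286, the smallest possible, adjusted p = 0.0429). The 4 affected females lay above all 4 control males. Of the X-linked genes 32.9% were called higher and 3.59% lower, against 8.79% and 10.8% of autosomal genes, and the medians of all 9 windows were positive. Camera gave p = 1.54e-12 with a preset correlation and p = 0.00486 with an estimated correlation. Genes reported to escape X inactivation rose for 12 of 19 and fell for 1 (13 and 1 adjusted over the list alone; camera adjusted p = 4.36e-08; adjusted p = 0.0455 with an estimated correlation). Xist is a member of this list, so its difference between the sexes is part of this result. The histone demethylase genes Kdm6a and Kdm5c and the translation factor gene Eif2s3x rose by 0.63 (SE 0.07), 0.71 (SE 0.10) and 0.88 (SE 0.13).

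**Figure D4:**
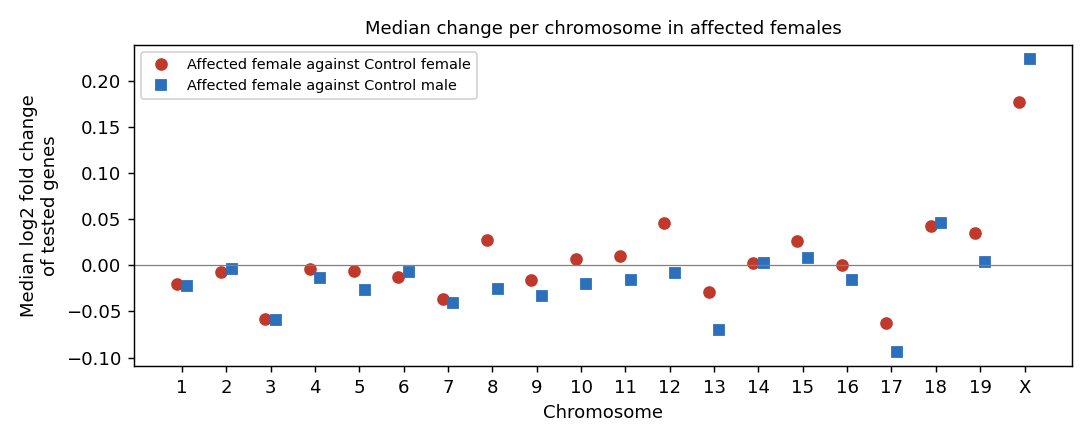
Median log2 fold change of the tested genes of each chromosome (horizontal axis) in affected females against control females (circles) and against control males (squares). Chromosome X lies highest in both, at 0.18 and 0.22, above all 19 autosomes.

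Early neuron markers fell for 17 of 26 members and rose for none in affected females against control males (19 fell adjusted over the list alone; camera adjusted p = 3.21e-06; adjusted p = 0.475 with an estimated correlation), with Nhlh1 at -2.12 (SE 0.33) and Neurod1 at -2.07 (SE 0.43). Control male 2 stood apart from the other control males for this list, with a list median of 0.75 against 0.05 to 0.17. It had 14.8 CPM of Nhlh2 against 5.72 to 6.27 CPM. Surface ectoderm and otic markers rose for 10 of 18 and fell for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 3.55e-05; adjusted p = 0.427 with an estimated correlation), with Esrp1, an epithelial splicing factor, at 0.78 (SE 0.16). Neural tube closure genes rose for 14 of 44 and fell for 2 (20 and 5 adjusted over the list alone; camera adjusted p = 0.000968; adjusted p = 0.475 with an estimated correlation), again with Cobl at 1.16 (SE 0.20) and Gli3 at 0.59 (SE 0.11). G2/M genes rose for 7 of 25 (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.77e-05; adjusted p = 0.475 with an estimated correlation), with Plk1 at 0.55 (SE 0.12) and Top2a at 0.47 (SE 0.12). Glycolysis and hypoxia genes rose for 11 of 24 and fell for 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00126; adjusted p = 0.514 with an estimated correlation), with Slc2a3 at 1.03 (SE 0.23). Ventral neural tube genes fell for 5 of 19 (7 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.475 with an estimated correlation), and Gli1 stood at -0.86 (SE 0.13). G1/S and S phase genes rose for 8 of 25 and fell for 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00745; adjusted p = 0.511 with an estimated correlation), and were not called without control male 2 (camera adjusted p = 0.0516). The G1/S list median of control male 4 was 0.14, within the 0.08 to 0.23 of affected females, against -0.21 to -0.06 in the other control males. Its medians were also the highest among control males for surface ectoderm and otic markers (0.06 against -0.36 to -0.12) and neural tube closure genes (0.06 against -0.18 to -0.06). The same held for G2/M genes (0.05 against -0.21 to -0.10) and neural crest markers (0.09 against -0.11 to -0.06), and for glycolysis and hypoxia genes (0.04 against -0.37 to -0.16). For ventral neural tube genes its median was the lowest among control males (-0.08 against 0.05 to 0.19), within the -0.25 to -0.04 of affected females. Neural crest markers rose for 3 of 16 and fell for 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00793; adjusted p = 0.475 with an estimated correlation).

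Further lists were called against control males. Silencing factors that act with Xist rose for 4 of 27 and fell for 1 (camera adjusted p = 0.018; adjusted p = 0.475 with an estimated correlation), with Dnmt1 at 0.58 (SE 0.12) and Smchd1, a gene needed to keep the inactive X silent, at 0.49 (SE 0.13). For this list the median of control male 4 was 0.04 against -0.09 to -0.06 in the other control males, above the -0.04 of affected female 1 and below the 0.05 to 0.13 of affected females 2 to 4. Integrated stress response genes rose for 4 of 17 (5 adjusted over the list alone; camera adjusted p = 0.0315; adjusted p = 0.511 with an estimated correlation) and were not called without affected female 1 (camera adjusted p = 0.0587) or control male 2 (0.0883). The median of control male 4 was 0.03 against -0.30 to -0.05 in the other control males and 0.08 to 0.10 in affected females. Dorsal neural tube genes fell for 3 of 18 (5 adjusted over the list alone; camera adjusted p = 0.0365; adjusted p = 0.511 with an estimated correlation), with Rspo3 at -0.88 (SE 0.20). They were not called without affected female 1 (0.126), affected female 2 (0.0913), control male 2 (0.0742) or control male 4 (0.142). The X inactivation centre set rose for 3 of 7 members (camera adjusted p = 0.00126; adjusted p = 0.309 with an estimated correlation), Xist and Tsix among them, and the 4 Y-linked genes were lower in affected females (camera adjusted p = 2.01e-10; adjusted p = 0.0455 with an estimated correlation). Of 38 p53 target genes, 2 rose and 3 fell (camera adjusted p = 0.828), and Ccng1 was lower in affected females than in control males by 0.39 (SE 0.10, adjusted p = 0.0203, edgeR). Of the 15 mitochondrially encoded genes 12 fell, with a median of -0.93. Mitochondrial counts made up 2.06% of the library of control male 4, against 2.82% to 3.82% in the other control males. In affected females the share was 1.31% to 1.69%.

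Both comparisons share the 4 affected females. Genes that differed from both control groups in the same direction numbered 2272, with 1012 higher and 1260 lower, and 6 genes went in opposite directions. Independent lists of these sizes would share 180 higher and 234 lower genes, and 20 simulations of unchanged groups with the same libraries gave at most 0 shared genes. The simulations drew each gene independently, so they lack the variation that the real libraries share across genes. They therefore cannot show how many shared genes such variation alone would give. Across genes, which are not independent replicates, the 2 sets of fold changes correlated with r = 0.79, against 0.46 in the simulations, and had a covariance of 0.18 against 0.02. When 2 affected females were set against control females and the other 2 against control males, the 6 splits gave 4 to 311 shared genes (median 33) and r between 0.65 and 0.70. The upward share of the shared genes, 44.5% with all libraries, was 31.3% to 47.2% leaving out 1 library. The shared count was 280 without affected female 3, 912 without affected female 4, 590, 944, 1215 and 3866 without control males 1, 2, 3 and 4 in turn, and 1205 and 1056 without control females 2 and 3. It was 5080 with limma voom and sample weights, 5138 with 1 contrast against the mean of both control groups, and 4597 without control female 1 and control male 4, an alternative added after the data were seen. Genes with strong evidence in both comparisons included Capn6, Irs4, Maob, Ets1, Zfp57, Entr1, Gprc5c, Bmf and Cnpy1. Zfp57, a zinc finger gene that keeps imprints methylated, fell to 38.1 ± 5.70 CPM from 106 ± 4.91 CPM in control females and 91.1 ± 32.3 CPM in control males. Cnpy1, a gene of the midbrain-hindbrain boundary, fell to 7.19 ± 2.51 CPM from 31.4 ± 6.89 and 27.6 ± 12.3 CPM.

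Control males and control females differ in sex and in p53 genotype, and few genes separated them. Of 14542 tested genes 21 changed, 7 upward and 14 downward in control males, and 891 had an unadjusted p under 0.05. The count was 35 without control male 2, 42 with DESeq2, 1569 with limma voom and sample weights, and 7 when only autosomal genes were counted. Xist and the 4 Y-linked genes differed as the sexes do, with Xist at -8.96 (SE 0.22). The other calls included the p53 targets Ccng1 at -1.52 (SE 0.10), Eda2r at -3.35 (SE 0.32) and Zfp365 at -0.97 (SE 0.16). Kdm6a stood at -0.61 (SE 0.08) and Mid1 at -2.68 (SE 0.25), and Arl5a and AA465934 rose by 0.61 (SE 0.11) and 2.41 (SE 0.20). As a set, p53 target genes were lower in control males, with 3 of 38 members called lower and none higher (10 lower adjusted over the list alone; camera adjusted p = 1.70e-14; adjusted p = 0.00137 with an estimated correlation). Genes of the X inactivation centre fell for 2 of 7 (3 adjusted over the list alone; camera adjusted p = 1.70e-14; adjusted p = 0.00315 with an estimated correlation), and genes reported to escape X inactivation for 3 of 19 (8 adjusted over the list alone; camera adjusted p = 1.84e-15; adjusted p = 0.00315 with an estimated correlation). Both lists hold Xist, Jpx and Ftx, so their results are not independent. No early neuron, neural tube closure or surface ectoderm marker was called, with camera adjusted p = 0.539, 0.496 and 0.086. With no member called over all genes tested, camera also called neural crest markers upward (adjusted p = 0.00682; adjusted p = 0.417 with an estimated correlation) and G1/S genes upward (adjusted p = 0.0189; adjusted p = 0.692 with an estimated correlation), both with 0 members adjusted over the list alone. It called integrated stress response genes downward (3 of 17 lower adjusted over the list alone; adjusted p = 0.0294; adjusted p = 0.692 with an estimated correlation). Neural crest markers lost that call without control male 4 (0.0634) or control female 3 (0.0839), G1/S genes without control male 4 (0.646) or control female 2 (0.0635), and integrated stress response genes without control male 2 (0.552) or control female 1 (0.764). The X-linked median was lower in control males by 0.05, a difference that did not pass the two-sided exact permutation test (p = 0.114). At an average log2 CPM over 4 the two-sided exact permutation test gave p = 0.0286. Camera on the X-linked genes pointed downward, with p = 0.00806 with a preset correlation and p = 0.18 with an estimated correlation.

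Genes that differed from control females in the same direction in both p53-/- groups numbered 15, with 3 higher and 12 lower. The count was 29 without control male 2, 23 with no low-count filter, 31 with DESeq2 and 1184 with limma voom and sample weights. The 3 higher genes were Gstm6 (a glutathione transferase of a multigene family, so reads may be shared with its relatives), Arl5a and AA465934. The lower genes with a symbol were Bcl2l11, Ccng1, Eda2r, Mid1, Erdr1 (pseudoautosomal, so its copies cannot be told apart), Gm4983, Xist and Tsix, and the other 4 had no symbol in the annotation used here. Control males also differ from control females in sex, so the falls of Xist (-8.96) and Tsix (-8.47) in control males cannot be ascribed to p53. Independent lists would share 0.909 higher and 2.10 lower genes and the simulations at most 0, with each gene again drawn independently. Since 3 control females cannot be split into groups of 2, part of the excess may come from the shared controls. Across genes, which are not independent replicates, the 2 sets of fold changes correlated with r = 0.50, below the 0.59 of the simulations. They had a covariance of 0.0792 against 0.0281.

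The spread of X-linked genes between embryos of a group was compared with that of autosomal genes of matched expression. The ratio of spreads was 1.05 in affected females, at the 96.6th percentile of 10000 random autosomal sets, 1.03 in control males (88.8th percentile) and 1.10 in control females (99.7th percentile). The order of affected and control females depended on the expression limit: at an average log2 CPM over 4 the ratio was 1.16 in affected females and 1.13 in control females.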

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

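Of the tests weighed in this part, the counts over other splits of the samples and the test of genes near Bcl2l11 were planned before their results were seen; the others were chosen only after the result was seen.

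A single library stood apart from the other 3 of its group (Dixon's gap test at the 95% level) in 12 of 240 sets of values, and chance alone gives about 1 in 20. Control male 2 had the highest early neuron list median of its group (0.75 against 0.05 to 0.17), the highest Nhlh2 (14.8 against 5.72 to 6.27 CPM) and Dll1 (86.9 against 50.5 to 56.1 CPM), the highest imprinted gene median (0.11 against -0.03 to -0.02) and the highest Xist (13.2 against 8.72 to 9.47 CPM). Affected female 1 had the highest BCL-2 family and caspase median (0.13 against 0.01 to 0.03) and the highest Sox10 (33.5 against at most 24.6 CPM). Affected female 2 had the lowest Esrp1 (32.0 against 40.0 to 40.9 CPM) and the highest Ring1 (15.6 against 14.1 to 14.3 CPM). Affected female 3 had the lowest endoderm and yolk sac median (-0.23 against 0.08 to 0.13). Affected female 4 had the highest Cnpy1 (10.9 against 5.78 to 6.16 CPM) and Nkx2-1 (7.36 against 5.48 to 5.78 CPM).

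Xist was lower and X-linked genes were higher in affected than in control females. Loss of an X chromosome in part of the cells is argued against by Kdm6a, Kdm5c, Eif2s3x and Ddx3x, for these genes alone. Their log2 fold changes were 0.02, 0.20, 0.39 and 0.49 (median 0.30), where the loss of 65.9% of Xist would need a median of -0.31. That value was taken from control males, which also differ from control females in p53 genotype. Of all 19 escape genes 6 were called higher and 6 lower, Xist and Mid1 among the lower. Male cells or a male library are argued against by the Y-linked genes, whose sum reached 0.314% of the lowest control male (0.897 against 286 CPM). A shift along an axis of 2043 autosomal genes that also varies among controls was weighed. These genes were chosen because they differed in affected females from both control groups in the same direction. The scores of affected females were thus set apart by that choice. The axis predicted an X-linked shift of 0.0838 (0.06 to 0.12 leaving out a control), less than the observed 0.18 by more than the mean SD of 0.05. The prediction used a common slope for both control groups, and affected females scored 0.65 to 0.97 on the axis against at most 0.25 in controls. It is therefore an extrapolation and cannot decide whether the axis accounts for the whole shift. Incomplete silencing of the X chromosome in affected females remains a hypothesis that gene counts cannot test; reads assigned to each parental allele or RNA FISH of X-linked genes would test it. The p53 genotype and the affected state cannot be separated here.

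Many genes differed between affected and control females. The real split called 4073 genes and the highest of the other 34 splits 0. Each other split mixes affected and control females within a group, which adds to the spread and lowers its count. The size of the gap therefore carries no weight, and only the rank does. The real split had the most genes of the 35, so chance is an unlikely cause of the count. With 35 splits the share that reaches the real count cannot fall below 1 in 35, so chance is not excluded. With length and GC trends removed 4362 genes were called, which argues against these trends as the whole cause. A difference in stage or cell mix may contribute: over 3709 autosomal genes called, the deviation of control male 4 from the other control males correlated with the change in affected females at r = 0.80 across genes, which are not independent replicates, with 95.6% of signs shared. The other control males had r = -0.41, -0.77 and 0.37 (replicates 1 to 3); each deviation is taken from the other control males, so these values are not independent of that of control male 4. For affected females against control males the real split called 2940 genes and the highest other 888, and again only the rank carries weight. Chance is again unlikely but, with 35 splits, not excluded. The split with 888 genes set affected female 1 and control males 1 to 3 against the rest. For control males against control females 4 of 35 splits called at least the real 21 genes, the highest 851, so chance could not be excluded for that count, and such counts point to a structure of the samples that does not follow sex or p53. The count of splits leaves single calls untouched: Xist, at -8.96 (SE 0.22), and the 4 Y-linked genes, at 7.96 to 9.75, follow the sex labels.

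Bcl2l11 was lower in both p53-/- groups although all groups carry the same Bim label. The log2 fold change in control males, -0.93, lay 0.63 SE from -1, and that in affected females 1.75 SE. A value of -1 would be that of Bim+/- embryos against Bim+/+ embryos, if the targeted allele gives no counts. The labels give Bim+/- for control females too, so the labelled genotypes do not account for the difference. The Bim genotype of the control females was not tested. Genes near Bcl2l11 showed no excess of changes that DNA of another strain there would predict. Of 194 tested genes within 10 Mb, 3 had an unadjusted p under 0.01, with 2.75 expected (exact hypergeometric test, p = 0.521). A count this near the expected one does not exclude such DNA. An effect of p53 loss on Bcl2l11 was not tested separately.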

How the results depend on the processing

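Removal of length and GC trends and omission of control female 1 with control male 4 were chosen only after the data were seen. No fold change or difference in the main results reversed direction under any alternative run, but the order of 2 spread ratios did, and the cause of the changes below was not tested unless stated. Genes changed in affected against control females numbered 1663 to 4957 leaving out 1 library, and 7639 with limma voom and sample weights (weights from 0.297 in control female 1 to 4.51 in control male 3), which called 4061 of the 4073. Affected females against control males gave 361 to 5140 leaving out 1 library, 6397 with voom, and 6014 without control female 1 and control male 4. Control males against control females gave 18 to 35, 42 with DESeq2, 1569 with voom, and 7 when only autosomal genes were counted, which are the autosomal calls of the main fit (3 higher and 4 lower). Genes differing from both control groups numbered 280 to 3866 leaving out 1 library, 5080 with voom, 5138 with 1 contrast against the mean of both, and 4597 without control female 1 and control male 4. Those differing from control females in both p53-/- groups numbered 13 to 29, 23 with no low-count filter, 31 with DESeq2 and 1184 with voom. Xist stayed between -1.68 and -1.41 leaving out 1 library, with the highest adjusted p at 0.00176 (edgeR). The X-linked minus autosomal difference stayed between 0.16 and 0.20 against control females and between 0.21 and 0.24 against control males; omission of a library from 4 against 3 cannot give an exact permutation p under 0.05. Between the control groups it ranged from -0.06 to -0.03, and reached p = 0.0286 in the exact permutation test at an average log2 CPM over 4 (-0.045). The spread ratio of X-linked genes in affected females was 1.01 to 1.07 leaving out 1 library and 1.16 over that expression limit, where control females had 1.13 and control males 1.06. Control females had the higher ratio without that limit (1.10 against 1.05), so the order reversed. With an estimated correlation the p53 target set in affected against control females had camera p = 0.00616 (adjusted p = 0.172 over 28 lists), and 0, 2 and 4 lists were called in the 3 comparisons. Among list results under alternatives 1077 were the same, 55 gained and 44 lost a call, and among named genes 6922, 156 and 358.

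The replicate number as a block gave 2875, 3418 and 21 genes in the 3 comparisons and Xist at -1.48. Same-numbered embryos correlated between -0.137 and 0.178 and 1 embryo correlated best with its own number. These values gave no sign of pairing by number, but the labels give no litter, so pairing cannot be excluded.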

Other observations

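The genes in this part were chosen after their values were seen, except those the naming rule took, and the test near Trp53 was chosen only after the result was seen. Among the 8 largest rises in affected females in both comparisons were Nup62cl, an X-linked nucleoporin-like gene, and Tcfl5, a transcription factor gene. Nup62cl reached 16.0 ± 2.96 CPM (SD, n = 4) against 4.72 ± 1.23 CPM in control males and 3.98 ± 2.86 CPM in control females. Tcfl5 reached 17.1 ± 6.07 CPM against 5.92 ± 1.22 and 4.89 ± 2.69 CPM. Shisa3, a regulator of Wnt and FGF signalling, fell to 1.12 ± 0.627 CPM from 4.84 ± 2.48 CPM in control males and 6.94 ± 4.39 CPM in control females. Among imprinted genes Plagl1, a zinc finger gene, fell to 97.1 ± 21.4 CPM from 166 ± 24.1 and 184 ± 31.9 CPM.

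Control female 1 differed from control females 2 and 3 in several lists. Its primitive erythroid median was -1.43 against 0.73 and 0.50, its glycolysis and hypoxia median 0.31 against -0.35 and -0.28, and its macrophage median -0.68 against 0.66 and 0.94. Control male 4 had the highest glycolysis and hypoxia median among control males, 0.04 against -0.37 to -0.16.

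Strain DNA flanking Trp53, carried along from the strain in which the mutation was made, is a hypothesis that predicts more changed genes near Trp53 in both p53-/- groups. Of 478 tested genes within 20 Mb, 10 had an unadjusted p under 0.01 in the same direction in both comparisons against control females, with 3.71 expected (exact hypergeometric test, p = 0.00406), which is consistent with it. The genes were Rabep1, Dgke, Smg8, Scpep1, Chd3, Trim25, Slfn9, Slfn10-ps, Gemin4 and AA465934. AA465934, Slfn9 and Trim25 had been seen to lie in this region before the test and its window were set, and they are among the 10 genes, so this p-value is too small as a test of the hypothesis. No other window was tried. Neighbouring genes are not independent, the comparisons share the control females, and in control males against control females only AA465934 passed the adjusted threshold (edgeR, adjusted p = 5.30e-06).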
